A study of Gallus gallus with 16 samples.

How the data were processed

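RNA from the duodenum of chickens of a low (LRFI) and a high (HRFI) residual feed intake line was measured on 16 one-colour Affymetrix chicken arrays, 4 per line at day 35 and 4 per line at day 42. The deposited data held a log2 value per probe set and array. Per the labels' protocols, total RNA was isolated with Trizol and 6 ug of it was made into biotin-labelled cRNA. Per the submitters' processing notes, the authors made the log2 values with Partek 6.5 and RMA, a method that corrects background, quantile normalizes the arrays and summarizes the probes of a set. The values were used as deposited, with no further normalization. Array medians lay between 5.05 and 5.10, single values between 2.10 and 14.75, and no value was missing. The median correlation of an array with the others, taken across probe sets, was between 0.978 and 0.991. Arrays give no read depth, so the number of arrays limits the precision.

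Samples were grouped by line and age from the labels. The labels do not say whether the arrays of a group came from separate birds. The p-values of single probe sets thus measure the spread between these arrays, which may be partly technical. They give no sex, hatch, slaughter or scan batch. Quantile normalization and summarizing by RMA compress differences of dim probe sets, and probes that match a bird's sequence poorly read low whatever the transcript's level.

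The 96 Affymetrix control probe sets were left out of the tests, which left 38439. The platform annotation gave 1 gene symbol to 27184 of these, several to 161 and none to 11094, for 13019 genes. Entrez identifiers matched 26858 probe sets to a RefSeq gene table of the assembly GRCg7b, which was used for names only and updated 5 symbols. No gene was named from a probe set with several symbols. Single probe sets were tested with limma 3.58.1 in R 4.3.3 (tables read with data.table, version 1.17.8). A model with 1 mean per group was fitted to all 16 arrays, so that the groups shared 1 estimate of the spread, and variances were moderated with eBayes. The 7 comparisons were LRFI against HRFI at each age and averaged over both, day 42 against day 35 in each line and averaged over both, and the interaction of line and age. P-values were adjusted by Benjamini-Hochberg over the 38439 probe sets in each comparison, and a probe set passed at an adjusted p under 0.05.

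Before the data were examined, 37 gene lists (pathways, cell types and complexes of the intestine), the tests, the comparisons and the rule for named genes were fixed. Lists with at least 5 measured genes were tested (36), with the probe set of the highest mean standing for each gene. The list test was camera, from limma, with a preset correlation of 0.01 between genes, adjusted over the lists in each comparison. It compares a list with all other genes and treats the genes as nearly independent, so its p-values rest on the spread between genes. Camera with a correlation estimated from the arrays was run beside this test, as was fry. Fry asks only whether the genes of a list move, on balance, one way. In the lists described the estimated correlation ran from 0.013 for fatty acid synthesis to 0.59 for proliferation genes. Adjusted p-values of single genes are from limma and those of lists from camera with the preset correlation unless stated otherwise. Counts such as 7 of 8 arrays give the arrays of the first-named line or later age that lay on the side of the other group's mean to which the list differed. A gene's p was also adjusted over the list alone. The ± values are SD between 4 arrays, unless another n is given, and the standard error (SE) of a difference is from the limma fit.

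Genes were named by a rule. Where fewer than 10 named probe sets passed in a comparison, which was so in each of the 7, the 5 with the smallest p in each direction were taken and described as not passing. From each list described, up to 4 members with the smallest p were taken. Uncharacterized loci were skipped and unnamed probe sets were counted. The 2 unnamed probe sets that passed, and the genes shown for pancreatic enzymes and switch-like probe sets, were chosen after their values were seen.

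The procedure was tested on simulated data with known answers, in which independent noise was drawn for all 38439 probe sets and 200 were changed. At day 35, the comparison of the lines called 35.8% of simulated differences of 0.5 log2, 83.6% of those of 1 and 98.5% of those of 2. For the average over both ages the shares were 65.7%, 91.0% and 98.5%, and for the interaction 8.96%, 74.6% and 93.9%. Real arrays differ in correlated ways that this simulation leaves out. The shares also hold only for 200 changed probe sets. Where fewer change, the adjustment is stricter and a difference of the same size passes less often. The shares therefore do not show that such differences would have been found in the real comparisons.

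The alternatives tried were a block for the replicate number, a trend and robust variance, unmoderated statistics, only brighter probe sets, 1 probe set per gene, a second quantile normalization, centring on array medians, array weights, only the groups compared, a minimum fold of 1.5, covariates for W-linked and for pancreatic genes, and each array left out in turn. After the data were seen, alternatives were added that corrected for the difference between 3′ and 5′ actin probe sets, a measure of RNA integrity and labelling, or that left out the 5 arrays where it exceeded 1 log2 or the 2 arrays with high pancreatic enzymes. Without the 5 arrays, day 35 kept only LRFI replicates 1 and 2 and HRFI replicates 1 and 4. A call lost there cannot be told apart from an effect of fewer arrays. Splits of the arrays were counted, the real one included. There were 35 for comparisons of 4 against 4 arrays, which are all of them, and 100 for the rest, of which all but the real one were drawn with seed 11.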

Results

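Residual feed intake is the feed a bird eats beyond what its body weight and growth predict, so that birds of a low line (LRFI) eat less than birds of a high line (HRFI) for the same growth. Gene expression was measured in the duodenum, the first part of the small intestine, of both lines at day 35 and day 42. There were 16 arrays, 4 in each of the 4 groups of line and age. Values are log2 expression levels, and a difference of 1 is a 2-fold difference. The median standard error of a difference was 0.12 for 4 against 4 arrays, 0.085 for the averages over 8 against 8 arrays and 0.17 for the interaction.

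Enzymes of the exocrine pancreas, which lies in the duodenal loop, were high on 2 arrays. The mean of the 19 pancreatic enzyme genes was 11.62 on HRFI day 35 replicate 3 and 9.47 on LRFI day 42 replicate 2, against 4.82 to 5.54 on the other 14. PLA2G1B, a secreted phospholipase, read 14.67 and 12.24 on these arrays against 6.05 ± 0.69 (SD, n = 14) on the others. PRSS2, a trypsinogen, read 14.27 and 13.05 against 3.82 ± 0.66, and CPA1, a carboxypeptidase, 14.06 and 11.40 against 4.63 ± 0.24. The 3′ actin probe set exceeded the 5′ one by over 1 on 5 arrays, 4 of them at day 35. The differences were 1.13 and 1.48 on LRFI day 35 replicates 3 and 4, 1.83 and 2.07 on HRFI day 35 replicates 2 and 3, and 1.20 on HRFI day 42 replicate 4. The other 11 arrays lay between 0.19 and 0.50. For GAPDH the same difference was 0.36 to 0.40 on the 4 LRFI day 42 arrays and at most 0.31 on the other 12. The W-linked gene HINTW, which is carried by female birds, read 3.88 to 4.59 on all 16 arrays, near the 25th percentile of all values (3.75).

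**Figure D1:**
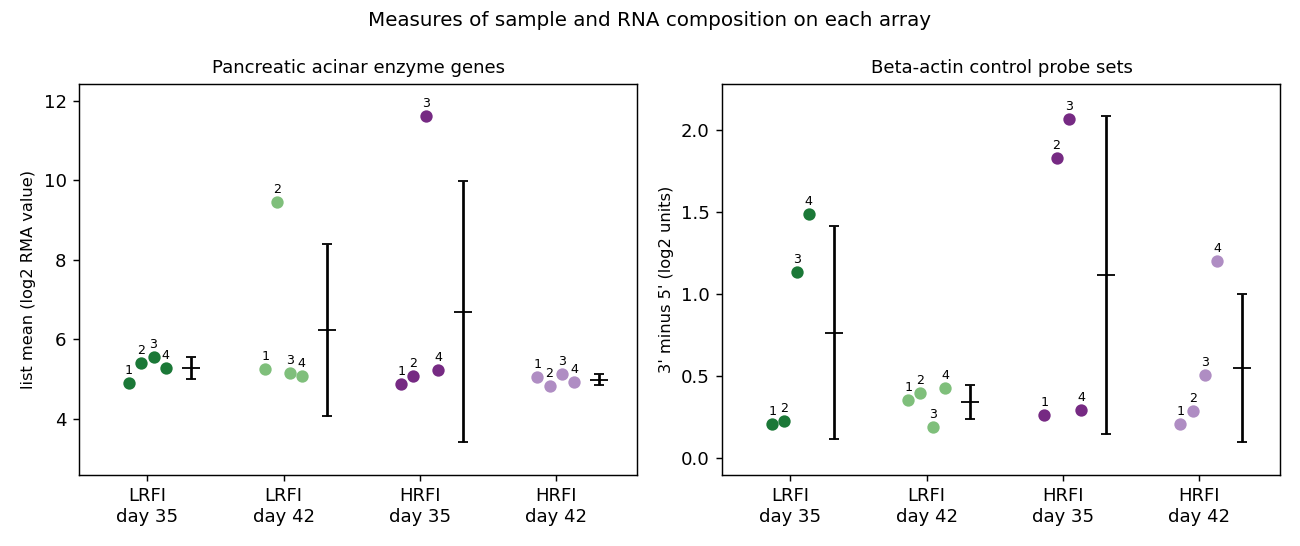
Each point is 1 of the 16 arrays in its group of line and age, with replicate numbers beside the points; bars give the group mean and SD (n = 4). The panels show log2 differences between 3′ and 5′ actin probe sets and log2 means of the 19 pancreatic enzyme genes, which read 11.62 and 9.47 on 2 arrays and 4.82 to 5.54 on the rest.

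The comparison of the lines at day 35 asks how duodenal expression differed with feed efficiency at the younger age. Genes of cell division, protein folding and inflammation had higher means in LRFI as groups, by a test that none of them passed with a correlation estimated from the arrays. Of 39 proliferation genes, 37 had higher means in LRFI and the average difference was 0.32 (adjusted p = 4.40e-12, or adjusted p = 0.573 with an estimated correlation). It turned to −0.077 (adjusted p = 0.27) without the 5 arrays with actin differences over 1, but was 0.35 (adjusted p = 7.18e-13) with the actin difference as a covariate and all arrays kept. It was 0.19 without LRFI day 35 replicate 3. Of 20 genes of the unfolded protein response and endoplasmic reticulum (ER) chaperones, 17 were higher, by 0.30 on average (adjusted p = 4.03e-08, or adjusted p = 0.519 with an estimated correlation), and all 4 LRFI arrays lay above the HRFI mean (9.73 ± 0.23 against 9.43 ± 0.15). Heat shock genes, whose products fold proteins in the cytosol and mitochondria, were higher in 18 of 20 cases (mean 0.24, adjusted p = 0.000414, or adjusted p = 0.573 with an estimated correlation). The LRFI arrays (9.69 to 9.74) lay within the range of the HRFI arrays (9.16 to 9.81), and without HRFI day 35 replicate 3, the array with the highest pancreatic enzymes and actin difference, the heat shock difference was 0.13 (adjusted p = 0.0225). Inflammatory mediators were higher in 20 of 29 (mean 0.43, median 0.10, adjusted p = 0.000577, or adjusted p = 0.573 with an estimated correlation), with all 4 LRFI arrays above the HRFI mean (7.08 ± 0.36 against 6.65 ± 0.19). Macrophage and granulocyte markers did not pass, at 7.70 ± 0.36 against 7.35 ± 0.27 (mean 0.35, median 0.080, adjusted p = 0.0808).

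Among the chaperones, HYOU1 was higher by 0.63 (SE 0.10), at 9.32 ± 0.14 against 8.69 ± 0.20. CALR, a calcium-binding chaperone, was higher by 0.63, HSPA5 by 0.52 and SDF2L1 by 0.52. These 4 passed when adjusted over the list alone (p from 0.000327 to 0.0482). In the inflammatory list 6 genes passed when adjusted over the list alone, among them EXFABP, a lipocalin (1.66, SE 0.35), AVD, which encodes avidin (2.33, SE 0.56), the chemokine IL8L2 (1.79, SE 0.47) and SAA, serum amyloid A (1.79, SE 0.54). In the proliferation list CCNE2 (0.46), RRM2 (0.56) and ANLN (0.87) passed when adjusted over the list alone, and TPX2, a spindle gene, differed by 0.80 without passing. No heat shock gene passed in that way, and HSPA4L (0.57), HSP90AA1 (0.40) and AHSA1 (0.31) came nearest with an adjusted p of 0.108. Proliferation differed among the LRFI arrays themselves: 2 of the 4 lay above the HRFI mean, and replicates 3 and 4, with actin differences over 1, read 8.33 and 8.19 against 7.59 and 7.60 for replicates 1 and 2. The HRFI arrays did not differ in this way, with 7.63 and 7.46 on replicates 2 and 3, whose actin differences were over 1, against 7.47 and 7.87 on replicates 1 and 4.

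Of the 36 lists, 11 passed at day 35, 8 higher and 3 lower. The others were fibroblast and matrix (0.19), erythrocyte (0.34), proteasome (0.11) and antioxidant genes (0.10), which were higher, and T and natural killer (NK) cell (−0.12), ribosomal protein (−0.044) and pancreatic genes (−1.42), which were lower, each with an adjusted p of at least 0.573 with an estimated correlation. No single probe set passed with limma, nor with trend and robust variances or unmoderated statistics, and 2561 had an unadjusted p under 0.05 where 1922 were expected by chance. The genes with the smallest p had adjusted p from 0.314 to 0.531. Besides HYOU1 they were MYBL1 (0.71), SERPINB10B (1.38, SE 0.25), IDH3B (0.58) and RBP4, a retinol carrier (1.98, SE 0.39), which were nominally higher in LRFI, and DELE (−0.68), BMP7 (−0.73), FRS3 (−0.47), TCF25 (−0.67, SE 0.15) and KATNIP (−0.39), which were nominally lower. No other probe set of BMP7, IDH3B, KATNIP or MYBL1 passed, and their estimates, some of each sign except for IDH3B (−0.066, SE 0.11), ran from −0.20 to 0.12. Nor did the other probe sets of FRS3 (−0.052, SE 0.094), TCF25 (−0.28, SE 0.13, and −0.050, SE 0.11) or HYOU1 (0.50, SE 0.17). Without HRFI day 35 replicate 3 the pancreatic difference turned to 0.22, and without the 2 arrays with pancreatic enzymes it passed as higher in LRFI (0.22, adjusted p = 0.00754). Without LRFI day 35 replicate 2 the inflammatory list no longer passed (0.28, adjusted p = 0.0595). Without the 5 arrays with actin differences over 1, LRFI replicates 1 and 2 were compared with HRFI replicates 1 and 4. In this smaller comparison 4 of the 11 lists passed in the same direction. They were ER chaperone, heat shock, inflammatory and ribosomal protein genes, the last at −0.078. Besides proliferation the pancreatic difference turned (0.097), and fibroblast (0.12, adjusted p = 0.134), erythrocyte (0.28, adjusted p = 0.273), proteasome (0.040, adjusted p = 0.27), antioxidant (0.089, adjusted p = 0.11) and T and NK cell genes (−0.16, adjusted p = 0.0726) did not pass. With the actin difference as a covariate, 10 of the 11 passed in the same direction, all but the pancreatic list (−0.92, adjusted p = 0.227). Among genes above the median level erythrocyte (0.49, adjusted p = 0.0661) and antioxidant genes (0.10, adjusted p = 0.0929) did not pass, nor T and NK cell genes with the mean of all probe sets of a gene (−0.11, adjusted p = 0.0603). Fibroblast genes did not pass without LRFI day 35 replicate 3 or HRFI day 35 replicate 1 or 3 (0.10 to 0.14). Antioxidant genes did not without LRFI day 35 replicate 3 or 4 or HRFI day 35 replicate 1 or 4 (0.044 to 0.091). Ribosomal protein genes did not without LRFI day 35 replicate 1 or HRFI day 35 replicate 2 (−0.025 and −0.032). Erythrocyte genes did not without LRFI day 35 replicate 1 or 3, HRFI day 35 replicate 1, 2 or 4 or HRFI day 42 replicate 1, 2 or 3 (0.27 to 0.38). T and NK cell genes did not without LRFI day 35 replicate 1, 3 or 4, HRFI day 35 replicate 3 or 4 or HRFI day 42 replicate 2 (−0.018 to −0.12), while their difference was −0.20 without HRFI day 35 replicate 2. The pancreatic list did not pass without LRFI day 35 replicate 1 or 3 (−1.29 and −1.51).

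At day 42 respiratory chain, cholesterol synthesis and heat shock genes were lower as groups in LRFI, and genes of xenobiotic metabolism were higher, again by a test that none of them passed with an estimated correlation. Of 54 genes of oxidative phosphorylation 45 were lower, by a small average of −0.097 (adjusted p = 5.84e-05, or adjusted p = 0.705 with an estimated correlation), and all 4 LRFI arrays lay below all 4 HRFI arrays (11.44 ± 0.06 against 11.54 ± 0.02). Of 18 genes of cholesterol synthesis and uptake 15 were lower (mean −0.31, adjusted p = 0.00016, or adjusted p = 0.705 with an estimated correlation), with all 4 LRFI arrays below the HRFI mean. Without LRFI day 42 replicate 3 the cholesterol difference was −0.19, and with the mean of all probe sets of a gene that of oxidative phosphorylation was −0.063. All 20 heat shock genes were lower (mean −0.21, adjusted p = 0.000447, or adjusted p = 0.555 with an estimated correlation), at 9.57 ± 0.11 against 9.78 ± 0.05. Of 26 genes of xenobiotic metabolism, which modify and export foreign compounds, 20 were higher (mean 0.17, adjusted p = 0.00203, or adjusted p = 0.555 with an estimated correlation), at 10.16 ± 0.05 against 9.99 ± 0.06. In the heat shock and xenobiotic lists the 4 arrays of each line did not overlap.

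No member of the 4 lists passed when adjusted over the list alone. The members with the smallest p were FDPS (−0.92, SE 0.28), HMGCS1 (−0.82), LSS (−0.56) and ACAT2 (−0.45) in cholesterol synthesis, AHSA1 (−0.40) among heat shock genes, NDUFA12 (−0.31) and ATP5C1 (−0.25) in oxidative phosphorylation, and CYP2C18 (1.04, SE 0.34), ABCC2 (0.45), ABCB1LA (0.35) and CYP3A5 (0.31) in xenobiotic metabolism. The day 42 LRFI arrays also had the 4 highest GAPDH 3′ to 5′ differences. Of the 36 lists, 8 passed, 4 in each direction. The others were lipid absorption (0.19), mineral and vitamin transport (0.12) and pancreatic genes (1.25), which were higher, and proliferation genes (−0.13), which were lower, with adjusted p of at least 0.705 with an estimated correlation.

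A single probe set passed at day 42, for which the annotation gave no gene. It was higher in LRFI by 2.46 (SE 0.31, adjusted p = 0.0296), at 6.35 ± 0.86 against 3.88 ± 0.42. The 2 other probe sets that share its cluster number in the array design were higher by 2.79 (SE 0.58) and 1.16 (SE 0.25) with an adjusted p of 0.606. In all, 2140 probe sets had an unadjusted p under 0.05, against 1922 expected. The named genes with the smallest p had an adjusted p of 0.606. Nominally higher in LRFI were DNAJC15 (0.67, SE 0.12), AADAC, a lipid and drug esterase (0.70, SE 0.14), TMEM55A (1.11), NFASC (0.53) and MLF1 (1.04), and nominally lower were CYYR1 (−1.07, SE 0.20), AMDHD2 (−0.54), SLC22A13L (−0.51), WDYHV1 (−0.65) and IGHMBP2 (−0.45). The other probe sets of IGHMBP2 did not pass and were at 0.13 (SE 0.10) and 0.15 (SE 0.13). Those of NFASC (0.17 and 0.084), SLC22A13L (−0.14 and −0.030), AMDHD2 (−0.37 and −0.53) and AADAC (0.76) did not pass either. The single call was lost with trend and robust variances, with unmoderated statistics and when any 1 array was left out other than LRFI day 42 replicate 1, 2 or 4 or HRFI day 42 replicate 2, and 5 probe sets passed when only the 8 day 42 arrays were fitted. Without LRFI day 42 replicate 2 the pancreatic difference was 0.17 (adjusted p = 0.432), but without the 2 arrays with pancreatic enzymes it passed at 0.17 (adjusted p = 0.0134). Proliferation genes no longer passed without LRFI day 42 replicate 4 (adjusted p = 0.338) or HRFI day 42 replicate 1 (adjusted p = 0.294), nor when corrected for the actin difference (−0.12, adjusted p = 0.0561). Mineral and vitamin transport did not pass with that correction (0.098, adjusted p = 0.0546) or without LRFI day 42 replicate 1 or HRFI day 42 replicate 1 or 3 (0.074 to 0.11).

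Averaged over both ages, the comparison gives the mean of the line differences at day 35 and day 42. Genes of connective tissue, of ER protein folding and of lipid absorption were higher as groups in LRFI on this average, by small amounts, and none passed with an estimated correlation (adjusted p = 0.773 with an estimated correlation for the 3 lists). Of 25 fibroblast and matrix genes 20 were higher (mean 0.14, adjusted p = 0.000941), and 6 of 8 LRFI arrays lay above the HRFI mean (8.61 ± 0.20 against 8.47 ± 0.21, n = 8). Of 20 ER chaperone genes 18 were higher (mean 0.11, adjusted p = 0.00471), with 7 of 8 LRFI arrays above the HRFI mean, but the line difference was 0.30 at day 35 and −0.089 at day 42, where it did not pass (adjusted p = 0.146), and the average was 0.072 without HRFI day 35 replicate 3. Of 17 genes of lipid absorption and lipoprotein assembly 13 were higher (mean 0.14, adjusted p = 0.00609), with 6 of 8, and the differences were 0.088 at day 35, which did not pass, and 0.19 at day 42. Fibroblast genes differed by 0.19 at day 35 and by 0.085 at day 42, which did not pass. Sugar, peptide and amino acid transporters, which take up digested nutrients, did not differ as a group (23 genes, mean −0.015, adjusted p = 0.925), and no comparison called them.

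Within lipid absorption, 2 genes passed when adjusted over the list alone. These were MTTP, which loads lipid onto lipoproteins (0.68, SE 0.15), and PLIN2, a lipid droplet coat protein (0.70, SE 0.19). SLC27A4, a fatty acid transporter, differed by 0.28 and SCARB1, a lipoprotein receptor, by −0.28. The matrix genes VCAN (0.38, SE 0.13), LUM (0.43), COL5A2 (0.22) and COL6A3 (0.27) did not pass in that way, nor did the chaperones HYOU1 (0.22) and CALR (0.31). The other 2 lists called were proliferation (34 of 39 genes higher, mean 0.094, adjusted p = 0.0031, 4 of 8 arrays; TPX2 0.54 and ANLN 0.44), whose line difference was called in opposite directions at day 35 (0.32) and day 42 (−0.13), and fatty acid oxidation (0.11, adjusted p = 0.0308), with adjusted p = 0.888 and 0.773 with an estimated correlation.

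No single probe set passed with limma for the average of the lines, nor with trend and robust variances or unmoderated statistics, and 2108 had an unadjusted p under 0.05 against 1922 expected. Adjusted p was 0.366 for TCF25 (−0.63, SE 0.11), which was nominally lower in LRFI, and 0.777 for the other named genes. These were STS, a steroid sulfatase (0.83, SE 0.17), DENND5B (0.61), MTTP, GSR, glutathione reductase (0.44, SE 0.098), and AADAC (0.43) on the higher side, and KCNJ15, a potassium channel (−1.68, SE 0.33), THEM4 (−0.33), FAT4 (−0.37) and DMA (−0.54) on the lower side. The other probe sets of FAT4, STS and THEM4 did not pass, with estimates from −0.11 to 0.063. Those of TCF25 were near 0, at −0.040 (SE 0.093) and −0.11 (SE 0.079), and those of DENND5B ran from 0.029 to 0.23. Other probe sets of AADAC (0.88), MTTP (0.34) and KCNJ15 (−0.61) did not pass either. Correction for the actin difference ended the calls of ER chaperones (0.066, adjusted p = 0.0552), lipid absorption (0.097, adjusted p = 0.0552) and fatty acid oxidation (0.080, adjusted p = 0.0614). Without LRFI day 35 replicate 2 ER chaperones did not pass (0.060, adjusted p = 0.135), and without LRFI day 35 replicate 1 or HRFI day 35 replicate 3 lipid absorption did not (0.10, adjusted p = 0.0937, and 0.094, adjusted p = 0.0504). Fatty acid oxidation did not pass among genes above the median level (0.10, adjusted p = 0.0768), nor without LRFI day 35 replicate 1, LRFI day 42 replicate 1 or 3, HRFI day 35 replicate 3 or HRFI day 42 replicate 3 or 4 (0.083 to 0.097). Proliferation was 0.12 (adjusted p = 0.000233) with that correction, but turned to −0.12 (adjusted p = 0.00248) without the 5 arrays with actin differences over 1 and did not pass without LRFI day 35 replicate 3 (0.027, adjusted p = 0.409) or 4 (0.050, adjusted p = 0.0966), nor without the 2 arrays with pancreatic enzymes (0.039, adjusted p = 0.15), while it was 0.15 without LRFI day 35 replicate 1 or 2.

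Within LRFI, the comparison of ages asks what differed in the duodenum between day 35 and day 42. Inflammatory genes were lower as a group at day 42 and genes of xenobiotic metabolism were higher, neither passing with an estimated correlation. Of 29 inflammatory mediators 25 were lower (mean −0.60, adjusted p = 1.75e-07, or adjusted p = 0.156 with an estimated correlation), and all 4 day 42 arrays lay below all day 35 arrays (6.48 ± 0.15 against 7.08 ± 0.36). Of 26 xenobiotic genes 21 were higher (mean 0.34, adjusted p = 1.44e-06, or adjusted p = 0.156 with an estimated correlation), at 10.16 ± 0.05 against 9.82 ± 0.21, and the difference was 0.19 (adjusted p = 0.00504) without the 5 arrays with actin differences over 1. Of 12 erythrocyte genes 10 were lower (mean −0.50, adjusted p = 0.00104, or adjusted p = 0.156 with an estimated correlation), at 6.27 ± 0.27 against 6.76 ± 0.22. Proliferation genes were lower in 36 of 39 (mean −0.25, adjusted p = 8.90e-06) and oxidative phosphorylation genes in 46 of 54 (mean −0.10, adjusted p = 5.34e-05), both with adjusted p = 0.485 with an estimated correlation. Without the 5 arrays with actin differences over 1 the proliferation difference turned to 0.078 (adjusted p = 0.102) and oxidative phosphorylation no longer passed (−0.0096, adjusted p = 0.421). With the actin difference as a covariate both passed (−0.22, adjusted p = 4.29e-05, and −0.071, adjusted p = 0.00102). The GAPDH 3′ to 5′ difference, which no setting corrected for, was 0.054 to 0.26 on the LRFI arrays at day 35 and 0.36 to 0.40 at day 42.

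By fry, inflammatory, xenobiotic and erythrocyte genes each moved one way (adjusted p = 0.0378 for each). Adjusted over the list alone, 9 inflammatory genes passed, all lower, among them EXFABP (−1.92, SE 0.35, from 8.77 ± 1.05 to 6.85 ± 0.21), IL8L2 (−2.24), AVD (−2.25) and NFKBIZ (−1.16), a regulator of inflammatory transcription. Adjusted over the list alone, 4 xenobiotic genes passed, all higher: the cytochrome P450 gene CYP2AC1 (2.0, SE 0.35, from 7.77 ± 0.86 to 9.77 ± 0.07), the efflux pump ABCG2 (0.49), FMO4 (0.58) and ALDH1A1 (0.61). The haemoglobin genes HBAD (−2.45, SE 0.62), HBA1 (−1.77, SE 0.55) and HBBR (−0.65) passed in the same way, as did CYCS, cytochrome c (−0.40, SE 0.094). No proliferation gene did, with ANLN (−0.76), KIF11 (−0.51), UHRF1 (−0.49) and CCNE2 (−0.42) nearest.

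Of the 36 lists, 15 passed in LRFI, 5 higher and 10 lower at day 42. The others were brush-border digestive enzymes (0.38), cholesterol synthesis (0.23), fatty acid oxidation (0.20) and mineral and vitamin transport (0.17), which were higher, and macrophage and granulocyte (−0.55), interferon response (−0.40), fibroblast (−0.24), ER chaperone (−0.18), smooth muscle (−0.17) and proteasome genes (−0.088), which were lower. Their adjusted p was at least 0.156 with an estimated correlation. No single probe set passed with limma or with trend and robust variances, 1 did with unmoderated statistics, and 3780 had an unadjusted p under 0.05 against 1922 expected. The named genes with the smallest p included CYP2AC1 and ACOX2, a peroxisomal oxidase of bile acid synthesis (1.11, SE 0.19, adjusted p = 0.161, from 7.97 ± 0.44 to 9.08 ± 0.22). OSBPL6 (1.22), SUCNR1 (0.90) and DDC, aromatic amino acid decarboxylase (0.89, SE 0.17), were nominally higher, and EXFABP, FKBP7 (−0.88, SE 0.14), SERPINB10B (−1.46, SE 0.25), RAB8A (−0.71) and the defensin AvBD4 (−0.91, SE 0.16) nominally lower. No other probe set of DDC or RAB8A passed: the brightest of DDC was at 0.83 (SE 0.26) and that of RAB8A at 0.13 (SE 0.11). Those of OSBPL6 (0.020 to 0.60), FKBP7 (−0.17 and −0.71), ACOX2 (1.14) and CYP2AC1 (2.82) did not pass either. Proliferation was −0.12 without LRFI day 35 replicate 3 and −0.17 without replicate 4, oxidative phosphorylation was −0.048 without replicate 4, and brush-border enzymes were 0.24 without it. Without the 5 arrays with actin differences over 1, the day 35 side held LRFI replicates 1 and 2 alone. In that setting 9 of the 15 lists passed in the same direction. Besides proliferation and oxidative phosphorylation, brush-border enzymes (0.048, adjusted p = 0.542), mineral and vitamin transport (0.060, adjusted p = 0.542), macrophage and granulocyte (−0.31, adjusted p = 0.0706) and proteasome genes (−0.023, adjusted p = 0.467) did not, and the values were −0.36 for ER chaperones, −0.26 for interferon response and 0.12 for fatty acid oxidation. With the actin difference as a covariate 14 of the 15 passed in the same direction. Proteasome genes did not pass with the mean of all probe sets of a gene (−0.052, adjusted p = 0.103). ER chaperones did not pass without LRFI day 35 replicate 1 or 2 (−0.15 and −0.083), nor proteasome genes without LRFI day 35 replicate 3 or LRFI day 42 replicate 3 (−0.061 and −0.056). Interferon response genes did not pass without LRFI day 42 replicate 2 (−0.24). Smooth muscle genes did not without LRFI day 35 replicate 2 or 3 or LRFI day 42 replicate 2 or 3 (−0.10 to −0.15). Mineral and vitamin transport did not without LRFI day 35 replicate 2 or 3, LRFI day 42 replicate 1, HRFI day 35 replicate 3 or HRFI day 42 replicate 2 (0.094 to 0.17). It was 0.26 without LRFI day 35 replicate 1 and did not pass when corrected for the actin difference (0.13, adjusted p = 0.0688). Cholesterol synthesis was 0.35 without LRFI day 42 replicate 3, and the fibroblast difference −0.14 without the 2 arrays with pancreatic enzymes and with the actin correction. The count of single probe sets was 33 without LRFI day 35 replicate 1, 2 without LRFI day 42 replicate 1 and 1 without LRFI day 35 replicate 2, 3 or 4.

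Within HRFI, cholesterol synthesis was the group with the smallest p between the ages, though it too did not pass with an estimated correlation. Of 18 genes of cholesterol synthesis and uptake 17 were higher at day 42 (mean 0.70, adjusted p = 2.51e-16, or adjusted p = 0.141 with an estimated correlation), and the day 42 arrays (9.57 to 9.90) lay above all day 35 arrays (8.54 to 9.39). Heat shock genes were higher in 17 of 20 (mean 0.30, adjusted p = 3.21e-06, or adjusted p = 0.141 with an estimated correlation), at 9.78 ± 0.05 against 9.48 ± 0.26, and by 0.20 without HRFI day 35 replicate 3. Fatty acid oxidation genes were higher in 16 of 19 (mean 0.22, adjusted p = 0.000472, or adjusted p = 0.141 with an estimated correlation), with all 4 day 42 arrays above all day 35 arrays (9.86 ± 0.13 against 9.63 ± 0.08), and fatty acid synthesis genes in 10 of 14 (mean 0.21, adjusted p = 0.00312, or adjusted p = 0.141 with an estimated correlation). ER chaperones (16 of 20, mean 0.22) and proliferation genes (33 of 39, mean 0.20) were higher too (adjusted p = 0.000356 for both, or adjusted p = 0.502 and 0.675 with an estimated correlation), the chaperones by 0.14 without HRFI day 35 replicate 3 and by 0.13 when corrected for the actin difference. Fatty acid synthesis differed by 0.14 with the mean of all probe sets of a gene.

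By fry, cholesterol and fatty acid synthesis (adjusted p = 0.0242 for both) and heat shock and fatty acid oxidation genes (0.0297 for both) moved one way. Adjusted over the list alone, 14 cholesterol genes passed, all higher. NSDHL, a sterol dehydrogenase, was higher by 1.18 (SE 0.17, from 9.28 ± 0.32 to 10.46 ± 0.30), SQLE, squalene epoxidase, by 1.48 (SE 0.29), LSS, lanosterol synthase, by 1.10 (SE 0.20) and MSMO1 by 1.13 (SE 0.25). Heat shock genes passing over the list alone numbered 8, among them HSPA4L (0.79), HSP90AA1 (0.61, SE 0.16), AHSA1 (0.48) and HSPA9 (0.38). In fatty acid oxidation 5 higher genes and 1 lower gene passed in this way, with CPT2 (0.40), SLC25A20 (0.55) and ACAA1 (0.51) among the higher, and in fatty acid synthesis FASN (0.84, SE 0.19) and ACLY (0.50, SE 0.15). HYOU1 (0.39) passed in the chaperone list and no gene in the proliferation list.

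Of the 36 lists, 12 passed in HRFI, 7 higher and 5 lower at day 42. The others were brush-border enzymes (0.22), which were higher, and pancreatic (−1.72), T and NK cell (−0.15), smooth muscle (−0.15), fibroblast (−0.14) and enteric neuron genes (−0.12), which were lower. None of these passed with an estimated correlation, where the smallest adjusted p in this comparison was 0.141 with an estimated correlation. No single probe set passed with limma, nor with trend and robust variances or unmoderated statistics, and 3183 had an unadjusted p under 0.05 against 1922 expected. NSDHL came nearest (adjusted p = 0.109), followed by other probe sets of SQLE (1.74, SE 0.28, adjusted p = 0.124) and LSS (1.37, SE 0.24, adjusted p = 0.159), and by IDI2, of isoprenoid synthesis (1.84, SE 0.31, adjusted p = 0.124), and PM5 (0.55). Nominally lower were TNPO1 (−0.43, SE 0.085), BCAS3 (−0.41), NCKAP5 (−0.58), GCNT2 (−0.66) and ASB1 (−0.54), with adjusted p from 0.213 to 0.273. No other probe set of NCKAP5, PM5 or TNPO1 passed. The brightest was at −0.15 (SE 0.15) for NCKAP5, 0.66 (SE 0.20) for PM5 and −0.76 (SE 0.16) for TNPO1. Other probe sets of BCAS3 (−0.037, SE 0.12), ASB1 (−0.10, SE 0.081), GCNT2 (−0.34 and −0.037) and IDI2 (1.57 and 1.0) did not pass either. The count was 1 without HRFI day 35 replicate 4, and 1 when only the 8 HRFI arrays were fitted. Without HRFI day 35 replicate 3 the pancreatic difference was −0.075 (adjusted p = 0.746), and T and NK cell (−0.14, adjusted p = 0.0521) and enteric neuron genes (−0.11, adjusted p = 0.116) did not pass, while smooth muscle was −0.23 and fibroblast −0.22. Without HRFI day 35 replicate 4, 8 of the 12 lists passed, and T and NK cell (−0.056), smooth muscle (−0.069), fibroblast (−0.053) and enteric neuron genes (−0.088) did not. Brush-border enzymes did not pass without HRFI day 35 replicate 1 or HRFI day 42 replicate 1, 3 or 4 (0.17 to 0.22). Smooth muscle genes did not without HRFI day 35 replicate 2 or HRFI day 42 replicate 1 or 3 (−0.13 to −0.14), nor fibroblast genes without HRFI day 35 replicate 2 or HRFI day 42 replicate 1 or 2 (−0.078 to −0.095). Enteric neuron genes did not without HRFI day 42 replicate 3 or 4 (−0.11 and −0.12). Corrected for the actin difference, brush-border enzymes (0.13, adjusted p = 0.0641) and enteric neuron genes (−0.087, adjusted p = 0.117) did not pass and the pancreatic difference was −0.91. Brush-border and enteric neuron genes also did not pass among genes above the median level (0.22 and −0.16, adjusted p = 0.0729 for both), nor brush-border enzymes with the mean of all probe sets of a gene (0.19, adjusted p = 0.0632). Without the 5 arrays with actin differences over 1 the pancreatic (−0.048, adjusted p = 0.996) and enteric neuron lists (−0.11, adjusted p = 0.205) did not pass, T and NK cell and smooth muscle genes were both at −0.29 and fibroblast genes at −0.25. T and NK cell genes were at −0.24 without HRFI day 35 replicate 2.

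Averaged over both lines, day 42 had higher means for lipid and xenobiotic metabolism genes and lower means for erythrocyte and inflammatory genes. None passed with an estimated correlation (adjusted p = 0.245 with an estimated correlation for inflammatory mediators and 0.114 for the other 5 lists). All 18 genes of cholesterol synthesis and uptake were higher (mean 0.47, adjusted p = 3.56e-13), and 7 of 8 day 42 arrays lay above the day 35 mean (9.57 ± 0.26 against 9.10 ± 0.26, n = 8). The cholesterol difference was 0.23 in LRFI and 0.70 in HRFI. Its interaction of −0.47 passed with the preset correlation and not with an estimated one. Fatty acid oxidation genes were higher in 16 of 19 (mean 0.21), at 9.90 ± 0.13 against 9.69 ± 0.10, and xenobiotic genes in 22 of 26 (mean 0.24), at 10.08 ± 0.10 against 9.83 ± 0.16 (n = 8, adjusted p = 2.12e-05 and 8 of 8 arrays for both). Fatty acid synthesis genes were higher in 10 of 14 (mean 0.18, adjusted p = 0.00432, 8 of 8 arrays). Inflammatory mediators were lower in 24 of 29 (mean −0.29, adjusted p = 4.01e-05, 8 of 8 arrays), but the levels went from 7.08 ± 0.36 to 6.48 ± 0.15 in LRFI and from 6.65 ± 0.19 to 6.67 ± 0.11 in HRFI (interaction −0.62, adjusted p = 0.000256, or adjusted p = 0.556 with an estimated correlation). Erythrocyte genes were lower in 12 of 12 (mean −0.34, adjusted p = 0.00187, 7 of 8 arrays). Taken alone, HRFI did not pass for erythrocyte (−0.19) or xenobiotic genes (0.14), nor LRFI for fatty acid synthesis (0.14). Of these 3 lists the interaction passed for xenobiotic genes (0.20, adjusted p = 0.0149, or adjusted p = 0.556 with an estimated correlation) and not for the others, and for xenobiotic genes it did not pass without the 5 arrays with actin differences over 1 (0.028, adjusted p = 0.733) but did with the actin difference as a covariate (0.21, adjusted p = 0.0125).

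By fry, fatty acid oxidation (adjusted p = 0.0117), cholesterol, xenobiotic and fatty acid synthesis (0.014 for each) and erythrocyte genes (0.0158) moved one way. Adjusted over the list alone, 13 cholesterol genes passed, all higher, among them NSDHL (0.84, SE 0.12), LSS (0.75, SE 0.14), DHCR7 (0.51, SE 0.10) and MSMO1 (0.78, SE 0.18). In fatty acid oxidation 8 higher genes and 1 lower gene passed, with EHHADH (0.44, SE 0.082), ETFDH (0.49), ECI2 (0.45) and ACAA1 (0.42) higher, and in fatty acid synthesis ME1, malic enzyme (0.49, SE 0.11), FASN (0.58, SE 0.14) and ACLY (0.31). In xenobiotic metabolism 8 higher genes and 1 lower gene passed, with ALDH1A1 (0.68, SE 0.14), CYP2AC1 (0.96, SE 0.25), UGT2A1 (0.65) and FMO4 (0.50) higher. The 5 inflammatory genes that passed were all lower, among them the chemokines CCL1 (−0.43) and IL8L2 (−1.25), SOCS1 (−0.65) and EXFABP (−0.85), as were the haemoglobin genes HBAD (−1.62, SE 0.44), HBA1 (−1.23) and HBBR (−0.36).

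**Figure D2:**
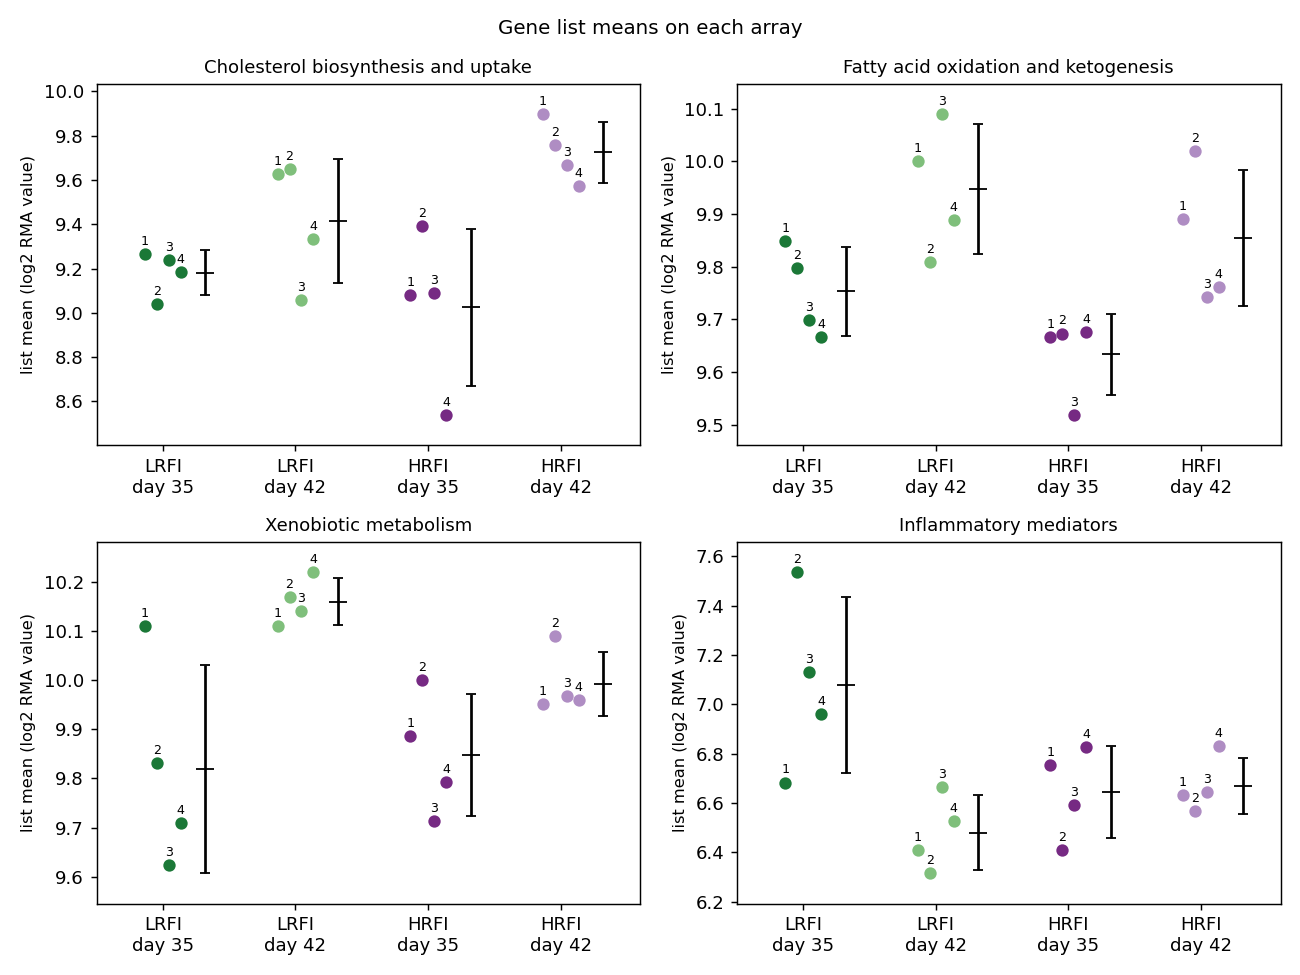
Each point is the mean log2 level of a gene list on 1 of the 16 arrays, by group of line and age; bars give the group mean and SD (n = 4). The cholesterol list was higher at day 42 than at day 35 in HRFI (9.57 to 9.90 against 8.54 to 9.39).

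Of the 36 lists, 16 passed for age averaged over the lines, 8 in each direction. The others were brush-border enzymes (0.30), circadian clock (0.15), lipid absorption (0.14) and heat shock genes (0.081), which were higher, and interferon response (−0.32), macrophage and granulocyte (−0.32), adipocyte (−0.20), fibroblast (−0.19), smooth muscle (−0.16) and oxidative phosphorylation genes (−0.039), which were lower. The lines went opposite ways in 2 of these. Heat shock genes went from 9.71 to 9.57 in LRFI and from 9.48 to 9.78 in HRFI. Oxidative phosphorylation genes went from 11.54 to 11.44 in LRFI and from 11.51 to 11.54 in HRFI. None passed with an estimated correlation, where the smallest adjusted p was 0.114 with an estimated correlation. A single probe set passed, which the annotation left unnamed. It was higher at day 42 by 0.62 (SE 0.075, adjusted p = 0.0162), going from 11.10 to 11.65 in LRFI and from 11.19 to 11.87 in HRFI. Of all probe sets 4530 had an unadjusted p under 0.05 against 1922 expected. NSDHL came next among named genes (adjusted p = 0.0543). ACOX2 (0.89, SE 0.14), DDC (0.77, SE 0.12) and another probe set of LSS (1.07, SE 0.17) had an adjusted p of 0.061, and MTMR14 (0.44) was nominally higher too. Nominally lower were GOLPH3L (−0.64, SE 0.11), MGP, matrix Gla protein (−0.56, SE 0.098), RAB8A (−0.49), AvBD4 (−0.62, SE 0.12) and PGGHG (−0.43, SE 0.083), with adjusted p from 0.061 to 0.0901. The brightest other probe set of RAB8A was at 0.14 (SE 0.078) and that of DDC at 0.84 (SE 0.18), and neither passed. The count of 1 moved to 45 without LRFI day 35 replicate 1, to 25 among brighter probe sets, to 15 with 1 probe set per gene and to 0 with unmoderated statistics. Oxidative phosphorylation turned to 0.00028 when corrected for the actin difference (adjusted p = 0.837) and to 0.028 (adjusted p = 0.364) without the 5 arrays with actin differences over 1. Circadian clock (0.12 and 0.078) and lipid absorption genes (0.065 and 0.059) passed under neither setting, and without the 5 arrays brush-border enzymes were at 0.14 and interferon response genes at −0.51. Without the 2 arrays with pancreatic enzymes, heat shock (0.017), lipid absorption (0.12) and oxidative phosphorylation genes (−0.038) did not pass. Among genes above the median level circadian clock (0.15, adjusted p = 0.104), lipid absorption (0.15, adjusted p = 0.0661) and heat shock genes (0.081, adjusted p = 0.0965) did not, nor circadian clock genes with the mean of all probe sets of a gene (adjusted p = 0.0683) or the replicate block (adjusted p = 0.0707). The circadian clock call ended with any 1 array left out other than LRFI day 35 replicate 1, LRFI day 42 replicate 1, 2 or 4 or HRFI day 35 replicate 2 (0.11 to 0.16). Heat shock genes did not pass without LRFI day 35 replicate 1, 2 or 4, LRFI day 42 replicate 2 or 3, HRFI day 35 replicate 1, 3 or 4 or HRFI day 42 replicate 3 or 4 (0.028 to 0.085), and were at 0.14 without HRFI day 35 replicate 2. Lipid absorption did not pass without LRFI day 35 replicate 2, 3 or 4, LRFI day 42 replicate 3 or 4, HRFI day 35 replicate 3 or 4 or HRFI day 42 replicate 1 or 3 (0.093 to 0.14). Oxidative phosphorylation did not without LRFI day 35 replicate 4, LRFI day 42 replicate 4, HRFI day 35 replicate 2 or 3 or HRFI day 42 replicate 1 (−0.010 to −0.037). The adipocyte call ended without LRFI day 35 replicate 1 or 2, LRFI day 42 replicate 4, HRFI day 35 replicate 1 or 2 or HRFI day 42 replicate 2 (−0.17 to −0.20), and those of interferon response (−0.20) and macrophage genes (−0.25) without HRFI day 35 replicate 4.

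The interaction asks whether the difference between the ages was unequal in the lines. Genes of cell division and the heat shock response were called higher in LRFI than in HRFI at day 35 and lower at day 42, and ER chaperones higher at day 35 but not different past the threshold at day 42. None of the interactions passed with an estimated correlation (adjusted p = 0.301 with an estimated correlation for ER chaperones and heat shock genes and 0.556 for proliferation and oxidative phosphorylation). For proliferation genes the line difference was 0.32 at day 35 and −0.13 at day 42, an interaction of −0.45 with 36 of 39 genes on the negative side (adjusted p = 3.20e-11). It was −0.093 (adjusted p = 0.215) without the 5 arrays with actin differences over 1 and −0.46 (adjusted p = 1.26e-10) with the actin difference as a covariate. For ER chaperones it was 0.30 and −0.089 (interaction −0.39, 19 of 20 genes), and for heat shock genes 0.24 and −0.21 (interaction −0.44, 19 of 20 genes), with adjusted p = 5.58e-07 for both. Oxidative phosphorylation genes had line differences of 0.033 and −0.097 (interaction −0.13, 46 of 54 genes, adjusted p = 8.09e-05), and the interaction was −0.074 without LRFI day 35 replicate 4 and −0.075 without the 5 arrays with actin differences over 1.

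Adjusted over the list alone, 4 chaperones passed: HYOU1 (−0.83, SE 0.15), HSPA5 (−0.72), SDF2L1 (−0.84) and CALR (−0.65). Among heat shock genes AHSA1 passed in this way (−0.71, SE 0.17), while HSPH1 (−1.34), HSPA4L (−0.92) and HSP90AA1 (−0.68) did not. No gene of the proliferation list did (SMC2 −0.81, RRM2 −0.69, CCNE2 −0.58, NUSAP1 −0.58), nor of oxidative phosphorylation (NDUFA12 −0.42). Of the 36 lists, 13 passed, 4 positive and 9 negative. No single probe set passed with limma, nor with trend and robust variances or unmoderated statistics, and 2438 had an unadjusted p under 0.05 against 1922 expected.

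The named gene with the smallest p for the interaction was AVD (−4.78, SE 0.79, adjusted p = 0.354). It read 10.33 ± 1.62 in LRFI and 8.0 ± 0.43 in HRFI at day 35, and 8.07 ± 0.50 and 10.53 ± 0.51 at day 42. HYOU1 followed (adjusted p = 0.518), then MYBL1 (−0.89), PGD (−0.81) and ATP1B3 (−0.98) on the negative side and HEBP2 (0.76), DELE (0.89), TNPO1 (0.56), HNRNPLL (0.51) and GCNT2 (0.92) on the positive side, with adjusted p of up to 0.539. No other probe set of HNRNPLL, MYBL1 or TNPO1 passed, and for each gene the estimates lay on both sides of 0. The brightest was at −0.10 (SE 0.15) for HNRNPLL and 0.62 (SE 0.22) for TNPO1. Other probe sets of HEBP2 (0.20), GCNT2 (0.24 and 0.34), ATP1B3 (−0.44) and HYOU1 (−0.64) did not pass either. The count of single probe sets was 8 without LRFI day 35 replicate 1, and 1 without LRFI day 35 replicate 4, HRFI day 35 replicate 2 or 4 or HRFI day 42 replicate 2.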

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

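The tests of line and age for the pancreatic enzymes and of the lowest array for the cholesterol genes were chosen only after the results were seen, as were the condition under which the line test of switch-like probe sets counts as open, the restriction of the test on other probe sets to those that are not switch-like, and the reading of a split count as void where the real count was 0.

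In the interaction of line and age, 13 gene lists differed by camera with the preset correlation, and with an estimated correlation adjusted p was 0.301 or above for each. Lower in LRFI, in the sense that the day 42 minus day 35 difference was smaller there, were inflammatory mediators (mean −0.62, median −0.11), macrophage and granulocyte markers (−0.47), cholesterol synthesis (−0.47), proliferation (−0.45), heat shock (−0.44), ER chaperones (−0.39), goblet cell genes (−0.19), proteasome (−0.15) and oxidative phosphorylation (−0.13). Higher were pancreatic enzymes (2.67), xenobiotic metabolism (0.20), T and NK cell markers (0.19) and ribosomal proteins (0.051). Without the 5 arrays with actin differences over 1, 8 of the 13 passed in the same direction, and proliferation (−0.093, adjusted p = 0.215), proteasome (−0.081, adjusted p = 0.15), macrophage (−0.040, adjusted p = 0.987), xenobiotic (0.028, adjusted p = 0.733) and pancreatic genes (1.13, adjusted p = 0.212) did not, while cholesterol synthesis was −0.70. With the actin difference as a covariate all 13 passed in the same direction. Goblet cell genes did not pass among genes above the median level (−0.25, adjusted p = 0.0981) or with the replicate block (−0.19, adjusted p = 0.0563), nor xenobiotic genes with the mean of all probe sets of a gene (0.17, adjusted p = 0.0872). Single arrays ended the calls of xenobiotic (LRFI day 35 replicate 3 or 4 or HRFI day 35 replicate 2, 0.13 to 0.16), T and NK cell (LRFI day 42 replicate 3 or HRFI day 35 replicate 3 or 4, 0.096 to 0.18) and ribosomal protein genes (LRFI day 35 replicate 1 or 2, LRFI day 42 replicate 2, HRFI day 35 replicate 2 or HRFI day 42 replicate 3, 0.030 to 0.041). They ended those of macrophage genes (LRFI day 35 replicate 2 or 3, LRFI day 42 replicate 1 or 2 or HRFI day 35 replicate 1, 2 or 3, −0.32 to −0.49) and goblet cell genes (all but LRFI day 35 replicate 4, LRFI day 42 replicates 2, 3 and 4 and HRFI day 42 replicates 2 and 4, −0.13 to −0.21). The pancreatic interaction was 1.03 without HRFI day 35 replicate 3, 1.59 without LRFI day 42 replicate 2 and −0.051 without both, and that of cholesterol synthesis −0.30 without HRFI day 35 replicate 4.

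In 23 of 588 groups of 4 arrays, 1 array stood apart, with a gap to its nearest neighbour that exceeded Dixon's critical value as a share of the group's range. Chance gives about 1 in 20 groups, or 29.4 here. The share of the range was 0.869 for ER chaperones and 0.886 for MTTP, 0.848 for EXFABP, 0.932 for GOLPH3L and 0.889 for ME1 on LRFI day 42 replicate 3, and 0.840 for EHHADH on LRFI day 42 replicate 2. On LRFI day 35 it was 0.836 for TCF25 (replicate 3) and 0.898 for NCKAP5 (replicate 4). On HRFI day 35 it was 0.939 for NCKAP5 (replicate 1), 0.837 for MLF1 and 0.898 for DHCR7 (replicate 2), and 0.937 for fatty acid oxidation and 0.864 for PLIN2 (replicate 3). On HRFI day 35 replicate 4 it was 0.900 for SQLE, which read 7.75 against a mean of 9.43 on the other 3, 0.867 for FASN, 0.923 for CENPF and 0.836 for HSPA9. On HRFI day 42 it was 0.882 for xenobiotic metabolism and 0.912 for FRS3 (replicate 2), 0.887 for TNPO1 and 0.903 for KIF11 (replicate 3), and 0.832 for DDC and 0.838 for CCNE2 (replicate 4).

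Pancreatic enzymes were high on HRFI day 35 replicate 3 and LRFI day 42 replicate 2, where 15 of the 19 genes exceeded all other arrays. Line and age do not account for it, since the other 6 arrays of these groups differed from the 8 arrays of the other groups by −0.025 (SE 0.11). Pancreatic tissue taken with the duodenum may be the source: of 12 genes outside the list raised at least 4-fold on the first array, 41.7% were raised at least 2-fold on the second, among them C6orf58 (8.28 and 4.75 above the others) and DNASE1 (6.41 and 2.17). On the other 14 arrays at most 16.7% were raised, but the share on the second array fell short of the level set for deciding, so the test leaves this open. Of the 19 genes 8 read above the lowest array median on the other 14 arrays, and no other list held any of them.

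Cholesterol synthesis genes were higher at day 42 averaged over both lines, by 0.47 (SE 0.12) for the list mean. The difference was 0.23 in LRFI and 0.70 in HRFI, and the tests below are on the average. A 3′ bias of the RNA that follows the actin difference linearly is argued against as the whole cause. The cholesterol difference was 0.53 (SE 0.13) after correction for the actin difference, above 0.23, which is 50% of the value without correction. A bias of another form, such as one that follows the GAPDH difference, was not tested. Without the 2 arrays with pancreatic enzymes it was 0.44 (SE 0.13), and without HRFI day 35 replicate 4, the array with the lowest list mean, 0.39 (SE 0.097), so each may account for a part and neither test settles how much. Age, feeding before collection and day of collection stay open as untested explanations, since the labels give neither of the last 2.

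A set of 15 probe sets split the arrays into a high and a low class at least 3 log2 apart. A sequence difference under the probes may be the source: of 8 other probe sets of SUCLG2, RHOG2, BLB1 and CYP2C23b, none of them switch-like and all at the same mean level or higher, 0% followed the split with r over 0.7, and the other 5 named genes had none to test. BLB1 was the only named gene with several switch-like probe sets, high on 6 and on 12 arrays. They were not set against each other, so for BLB1 the test left out the probe sets most able to follow. SUCLG2 was high on 10 arrays (11.22 against 3.94) and MHCY4 on 13 (11.95 against 5.53). For the line of the birds the smallest adjusted Fisher exact p, two-sided, was 0.6. Only 6 of the 15 could have reached an unadjusted p under 0.05 with 8 arrays per line, so the bound first set for excluding line was wrong by design, and line stays open.

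Splits of the arrays into groups of the same sizes were counted for each comparison, and the counts and totals below include the real split. For single probe sets called, chance could not be excluded at day 42, where 4 of 35 splits called at least as many (1 real, 3 highest other), or for age over both lines, 10 of 100 (1 and 2). The real split called 0 in the other comparisons, so that all splits called as many by construction and the count tests nothing there: 35 of 35 at day 35 (1664 highest other), 35 of 35 for age in LRFI (18), 35 of 35 for age in HRFI (1), 100 of 100 for the line average (87) and 100 of 100 for the interaction (666). The split with 1664 calls set the 4 day 35 arrays with actin differences over 1 against the other 4, and the splits with 87 and 666 calls kept these 4 arrays together on 1 side too, which points to a structure of the day 35 arrays that crosses the lines.

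For gene lists called, 4 of 100 splits, the real one among them, gave as many for age averaged over both lines (16 real, 17 highest other), a share so near 0.05 that 100 splits exclude chance narrowly at best. It could not be excluded at day 35 (12 of 35 splits, 11 and 15), at day 42 (7 of 35, 8 and 14), for the line average (82 of 100, 5 and 16), for age in LRFI (5 of 35, 15 and 19), for age in HRFI (4 of 35, 12 and 15) or for the interaction (8 of 100, 13 and 17). Nor could it for the count of probe sets at an unadjusted p under 0.05, in which 11 of 35 splits at day 35 (2561 real, 8248 highest other), 2 of 35 at day 42 (2140 and 2201), 25 of 100 for the line average (2108 and 4908), 6 of 35 for age in LRFI (3780 and 5714), 4 of 35 for age in HRFI (3183 and 3524), 6 of 100 for age over both lines (4530 and 6502) and 17 of 100 for the interaction (2438 and 6803) gave as many.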

How the results depend on the processing

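Corrections for the actin difference and the settings that leave out the 2 arrays with pancreatic enzymes or the 5 with actin differences over 1 were chosen after the data were seen. The cause of the moved values below was not tested, unless the setting names fewer arrays or genes. Log2 differences of named genes kept their direction in all settings. This was likely beforehand, since the genes were chosen for a small p on these arrays. Each gene was counted once per comparison and setting, so 1 gene can appear many times. Of these values 34 passed that had not in the first fit, and 2762 still did not. With 1 array left out, 38 passed and 3082 did not. Of 720 values of called gene lists under settings that kept or left out sets of arrays, 491 stayed past the threshold in the same direction, 219 did not pass and 10 turned, and 148 of the 219 were lost with an estimated correlation or by fry. With each array left out, 1132 stayed, 147 did not pass and 1 turned. Signal over background was not tested, since the deposited table held only summarized values.

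The count of called probe sets at day 42 between the lines (1) became 0 with trend and robust variances, unmoderated statistics, only brighter probe sets, 1 probe set per gene, the W-linked covariate, the pancreatic covariate, without the 2 pancreatic arrays or without the 5 actin arrays, 3 without the 2 pancreatic arrays and with the actin covariate, and 5 with only the groups compared. The count for age over both lines (1) became 6 with trend and robust variances, 0 with unmoderated statistics, 25 with only brighter probe sets, 15 with 1 probe set per gene, 2 when quantile normalized again, 4 with the W-linked covariate, 0 with the actin covariate, 0 without the 2 pancreatic arrays, 0 with both, and 9 without the 5 actin arrays. These 9 did not include the probe set that passed with all arrays. Among them were GSTA4 (1.55, adjusted p = 0.00892), GSTT1L (2.02, adjusted p = 0.00892) and EHHADH (0.57, adjusted p = 0.0198), which were higher, and SERPINB10B (−1.03, adjusted p = 0.019), which was lower. SERPINB10B also passed for age in LRFI without these arrays (−1.70, adjusted p = 0.00909). Counts of 0 became 1 for the line average and for age in LRFI without the 5 actin arrays, for age in LRFI with unmoderated statistics, for age in HRFI with 1 probe set per gene and with only the groups compared, and for the interaction when quantile normalized again and with array weights, and 2 for the interaction with the W-linked covariate. A minimum fold of 1.5 and centring on array medians moved no count.

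With the replicate number as a block, the counts were 0 at day 42, 1 for the line average, 11 for age in HRFI and 19 for age over both lines, and the others did not move. Correlations over all probe sets gave no sign that the numbers pair the arrays: of 24 same-number pairs 6 correlated over 0.1 (r from −0.31 to 0.33), and 4 of 16 arrays correlated best with their own number. The mean r was −0.0092 for same-number pairs and 0.0036 for the others. Such correlations cannot exclude a pairing that touches a part of the probe sets.

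The count of lists was 0 in all 7 comparisons with an estimated correlation. By fry it was 0 at day 35, 0 at day 42, 0 for the line average, 3 for age in LRFI, 4 in HRFI, 5 over both lines and 0 for the interaction. Of the 80 calls, 9 ended among genes above the median level, 5 with the mean of all probe sets of a gene and 2 with the replicate block. The count was 3 for the line average with the actin covariate, and without the 5 actin arrays 7 at day 35, of which 4 were among the 11 called with all arrays, and 9 for the line average, of which 4 were among its 5 in the same direction. Without those 5 arrays proliferation turned to −0.077 at day 35, −0.12 for the line average and 0.078 for age in LRFI. Oxidative phosphorylation, for age over both lines, turned to 0.00028 with the actin covariate and 0.028 without the 5 arrays. Pancreatic enzymes at day 35 turned to 0.22 without the 2 pancreatic arrays, 0.23 with the actin covariate as well and 0.097 without the 5 actin arrays, and to −0.051 and −0.037 for the interaction under the first 2. With each array left out the day 35 pancreatic difference ran from −2.03 to 0.22, the latter without HRFI day 35 replicate 3.

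With each array left out in turn, counts ran from 0 to 5 at day 35, 0 to 1 at day 42, 0 to 1 for the line average, 0 to 33 for age in LRFI, 0 to 1 for age in HRFI, 0 to 45 for age over both lines and 0 to 8 for the interaction, and list counts from 7 to 14, 6 to 12, 4 to 10, 12 to 17, 8 to 14, 11 to 16 and 9 to 15. At day 35 the count was 5 without LRFI day 35 replicate 1, 4 without HRFI day 35 replicate 2, and 1 without LRFI day 35 replicate 3 or 4 or HRFI day 35 replicate 4. At day 42 it was 0 without any day 35 array, LRFI day 42 replicate 3 or HRFI day 42 replicate 1, 3 or 4. For the line average it was 1 without LRFI day 35 replicate 4, LRFI day 42 replicate 1 or HRFI day 35 replicate 4. For age in LRFI it was 33 without LRFI day 35 replicate 1, 2 without LRFI day 42 replicate 1 and 1 without LRFI day 35 replicate 2, 3 or 4, and in HRFI 1 without HRFI day 35 replicate 4. Over both lines it was 45 without LRFI day 35 replicate 1, 8 without LRFI day 35 replicate 2 or HRFI day 42 replicate 4, 7 without HRFI day 35 replicate 2, 4 without LRFI day 42 replicate 3, 3 without HRFI day 35 replicate 1, 2 without LRFI day 35 replicate 4, LRFI day 42 replicate 1 or HRFI day 35 replicate 4, and 0 without LRFI day 42 replicate 2 or 4 or HRFI day 42 replicate 1. For the interaction it was 8 without LRFI day 35 replicate 1 and 1 without LRFI day 35 replicate 4, HRFI day 35 replicate 2 or 4 or HRFI day 42 replicate 2. The list count was 7 at day 35 without LRFI day 35 replicate 3, and for the line average 10 without LRFI day 35 replicate 2 or HRFI day 35 replicate 2 and 8 without LRFI day 42 replicate 4 or HRFI day 35 replicate 4. The cholesterol list passed for age over both lines without any 1 array, with means of 0.39 to 0.53.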

Other observations

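Several groups of genes with known roles in the duodenum passed in none of the 7 comparisons. Glycolysis genes came nearest in the interaction (16 genes, adjusted p = 0.0605), and genes of major histocompatibility complex antigen presentation in the line average (12 genes, mean −0.088 in LRFI against HRFI, adjusted p = 0.0816). The smallest adjusted p over the comparisons was 0.16 for B and plasma cells, 0.186 for energy-sensing and growth-factor signalling (41 genes), 0.197 for crypt and stem cells, 0.27 for sugar, peptide and amino acid transporters, 0.28 for endothelial cells, 0.339 for distal gut, 0.445 for enteroendocrine and 0.474 for proximal gut markers. A list that did not pass is not shown to be equal between the groups.

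Interferon response genes, which are induced by virus and cytokines, were lower at day 42 in LRFI in 28 of 30 (mean −0.40, adjusted p = 0.00104, 0.495 with an estimated correlation), and over both lines in 24 of 30 (mean −0.32, adjusted p = 0.00119, 0.588 with an estimated correlation). The second call was lost without HRFI day 35 replicate 4 (−0.20, adjusted p = 0.0607) and the first without LRFI day 42 replicate 2 (−0.24, adjusted p = 0.052). Brush-border digestive enzymes, which finish the digestion of sugars and peptides, were higher at day 42 in 12 of 13 genes over both lines (mean 0.30, adjusted p = 0.000167, 0.245 with an estimated correlation). On the LRFI day 35 arrays with actin differences over 1 their mean was 10.03 and 9.84, against 10.59 on each of the other 2. The HRFI arrays showed no such gap, with 10.35 and 10.31 against 10.17 and 10.45 at day 35 and 10.53 against 10.52 to 10.57 at day 42.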
